A study of Mus musculus with 4 samples.

How the data were processed

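The data came from mouse E14TG2a embryonic stem cells at day 0 (with LIF) and day 6 (without LIF), with 1 hairpin bisulfite library and 1 RNA library per state, 4 samples in all. Groups were taken from the sample titles. Per the labels' protocols, genomic DNA was sonicated, ligated to a biotinylated hairpin adapter and to sequencing adapters, digested with MseI and MluCI, pulled down on streptavidin beads, converted with bisulfite and amplified by 12 cycles of PCR, followed by size selection. The digestion leaves fragments without the recognition sites of those enzymes, so the genome is covered in part.

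Bowtie, TopHat2 2.0.3 and Cufflinks 2.0.2 were used with the build mm10, per the submitters' processing notes. Which tool served which step and with which parameters is not given in the sources used here. Per the file headers, the deposited CpG tables hold counts of hairpin reads per dyad in 4 states (both strands methylated, the first only, the second only, neither), and the fraction of methylated cytosines and the fraction of dyads with like strands. Both deposited fractions were recomputed from the counts and differed by at most 5.6e-16. The deposited non-CpG tables hold counts of all reads and of methylated reads per cytosine, per the file headers. Every position was in both libraries with at least 5 reads in each, so sites with fewer reads in either library were left out before deposition. All 3605386 CpG positions are a CG in the reference when counted from 1. The RNA values were deposited by the authors as normalized RPKM per UCSC transcript. Their sum was 841012.7 in both libraries, and 96.9% of sorted values were equal within 1e-06, so that the authors' normalization had given both libraries the same distribution. It removes any difference in total RNA and in the shape of the distribution. Depth in reads is unknown for RPKM, so no counting interval is given for expression.

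Sequence and annotation came from GRCm38.p6 with GENCODE vM21, the same build, and RefSeq transcripts of that build were also used to match symbols. Transcripts were given a gene symbol where their ends equalled those of an annotated transcript or overlapped one reciprocally by at least 0.8 of both lengths. This matched 83.2% of 58874 transcripts to 24802 symbols, and values were summed per symbol. Unmatched transcripts held 46.9% of the summed RPKM at day 0 and were left out. In a check with 2000 annotated transcripts whose ends were shifted slightly, 99.9% were matched to the right gene. The unshifted transcripts were in the annotation searched, so the check says little about deposited transcripts matched at lower overlap.

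CpG dyad counts were pooled over sites. The methylation level was the share of methylated cytosines, fidelity the share of dyads with like strands, and the hemimethylated share was taken over all dyads and over dyads with any methylation. Libraries were compared with two-sided Fisher's exact tests and exact Clopper-Pearson intervals, and strands with exact binomial tests. These were joined, after the data had been seen, by 1000 bootstrap draws of 1 Mb blocks, whose 95% intervals are the ones given. In 200 simulated data sets, 94.5% of such intervals held the true share. Sites were classed as promoter (1000 bp upstream to 500 bp downstream of the start of a protein-coding gene), exon, intron or intergenic, in that order, by CpG density (in 500 bp: high at an observed over expected CpG ratio of at least 0.75 with a GC share of at least 0.55, low at a ratio under 0.48) and by repeat masking in the reference.

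Single dyads (at least 10 reads in each library), windows of 10 kb and promoters (at least 20 reads) were tested with Fisher's exact test and Benjamini-Hochberg adjustment at 0.05. On simulated reads of chromosome 19 (53586 dyads), 93.0% of changes from 90% to 30%, 22.0% of changes from 90% to 60% and 0.00187% of unchanged dyads were called, but 22.0% of unchanged dyads when all reads came from 3 molecules per dyad. PCR copies were therefore measured. Of dyads with at least 5 hemimethylated reads, 75.7% at day 0 and 86.2% at day 6 had all of them on 1 strand, against 2.17% and 1.46% for independent reads. The majority strand was the same in both libraries at 52.5% of shared dyads. The share of read pairs on opposite strands gave the number of effective molecules per dyad, a model that takes the hemimethylated share as equal across dyads. Tests were repeated with reads reduced to that number, for regions with 1 dyad per 200 bp and at least 5 molecules. Effective molecules are an approximation. The reduced test counts both cytosines of a molecule as 1 observation, which lowers its power. It also uses 1 value per library, weighted to dyads with many reads, which overstates the molecules of dyads with few reads.

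Non-CpG calls were pooled by the reference bases around each cytosine. The table named CHG held CAG and CTG only, and CCG was in the table named CHH. The unmethylated lambda DNA spiked into the libraries was not used here, so conversion was judged from CC cytosines. The conversion alternative instead used the methylated share of the whole table named CHH, 1.48% at day 0 and 1.35% at day 6. That share includes calls at CA. Windows of 1 Mb were compared with the 50 autosomal windows closest in CpG density and GC content.

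Expression differences were log2((day 6 RPKM + 1) / (day 0 RPKM + 1)) for genes with at least 1 RPKM in 1 of the libraries, with no test. A gene under 1 RPKM in 1 library passes only through the other, which fixes its direction. Counts of higher and lower list members include such genes. The 21 gene lists were naive pluripotency, core pluripotency, formative and primed epiblast, LIF and STAT3 pathway, primitive streak and mesoderm, cardiac and smooth muscle, endoderm, neuroectoderm, trophoblast, Hox genes, 2-cell-like, germline genes, DNA methylation maintenance, de novo DNA methylation, TET oxidation and base excision, imprinted genes, cell cycle, extracellular matrix and epithelial-mesenchymal transition, blood with endothelium and macrophage, stress and apoptosis, and a housekeeping reference. A list stood apart when its median lay at or under percentile 2.5 or at or over percentile 97.5 of 10000 random lists matched in 20 bins of mean expression. In simulated data on the 12212 genes, 10 of 10 lists of 20 genes moved by 1 on the log2 scale and 1 of 40 unmoved lists stood apart.

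Gene lists, tests, thresholds and most alternatives were chosen before the data were examined. So was the rule for named genes: the 10 largest differences each way among genes with at least 5 RPKM in 1 of the libraries (without predicted genes, pseudogenes and the families Mir, Snor and Rnu), every measured member of the 3 methylation lists, up to 4 members of each other list by size of difference, the 5 promoters and 5 windows with the largest differences each way with at least 50 reads, promoters of the naive, germline and methylation lists with up to 4 examples, and up to 3 dyads each way by p. Of the windows and dyads, the first each way is given. Scarna8 is a small RNA that the rule did not leave out. Alternatives varied coverage minimum, weighting of sites, chromosomes, high-coverage sites, conversion, region size, centring, unit counted, pseudocount, filter, scaling, the choice between transcripts of a gene and the promoter window. Added after seeing the data were dyads with equal reads, effective molecules, the genome without chromosome 8 and the block bootstrap. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, pyarrow 21.0.0 and matplotlib 3.10.9.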

Results

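The series profiled mouse embryonic stem cells of the line E14TG2a in 2 states. E14TG2a is a male line that lacks a functional Hprt gene and grows without feeder cells. Undifferentiated cells (day 0) were cultured with leukemia inhibitory factor (LIF), the cytokine that holds mouse embryonic stem cells in self-renewal. Day 6 cells had been kept without LIF for 6 days and had differentiated spontaneously. Each state had 1 hairpin bisulfite library and 1 RNA library, so no difference between the states has a replicate check, and a test on reads compares the libraries, not the conditions. In hairpin bisulfite sequencing, a hairpin adapter ties both strands of a DNA fragment together before conversion, so that 1 read reports both cytosines of a CpG dyad, which is then fully methylated, hemimethylated or unmethylated. The CpG data covered 3605386 dyads in both libraries, with 58493671 dyad reads at day 0 (median 13 per dyad) and 75489380 at day 6 (median 16). The non-CpG data covered 35228969 cytosines in CAG and CTG and 115745872 cytosines in the other non-CpG contexts. In the RNA libraries, 12212 genes reached 1 RPKM in at least 1 library. Hprt was listed at 0.353 RPKM at day 0 and 0.473 RPKM at day 6.

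The first comparison asked how gene expression differed after 6 days without LIF. Transcripts of the pluripotency network were lower at day 6, and transcripts of primitive streak and mesoderm genes and of smooth muscle genes in the cardiac and smooth muscle list were higher. The naive pluripotency regulator Esrrb (chromosome 12, 86361117 to 86521628) went from 109.5 to 5.44 RPKM, a log2 difference of -4.10, and Nr0b1, a nuclear receptor of the same network, from 66.6 to 3.45 RPKM. Wnt6 (chromosome 1, 74771892 to 74785322), a secreted WNT ligand, was listed at 0.507 RPKM at day 0 and 70.2 RPKM at day 6, a log2 difference of 5.56. The epithelial keratins Krt8 and Krt18 went from 24.6 to 703.9 RPKM and from 56.9 to 1327 RPKM. All differences are on the log2(RPKM + 1) scale, which understates the change of genes at low values.

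Among genes with at least 5 RPKM in 1 of the libraries, the other genes with the 10 largest positive differences were Sprr2a3, a cornified-envelope protein (log2 difference 5.18), the skeletal and smooth muscle actins Acta1 (5.03) and Acta2 (4.89), the small heat-shock protein Cryab (4.79), the chemokine Cxcl10 (4.76), the macrophage growth factor Csf1 (4.42) and the primitive streak ligand Wnt3 (4.40). Among the 10 largest negative differences were the protease inhibitor Spink1 (-4.25), the aspartic protease Napsa (-4.07), Tcl1, an activator of AKT kinase (-3.96), the sarcosine oxidase Pipox (-3.88), the zinc finger factor Sall1 (-3.85), the efflux transporter Abcc4 (-3.76) and the fusion protein gene Mymx (-3.70). The small nuclear RNA gene Scarna8 was at 67.2 RPKM at day 0 and listed at 0 at day 6. Counted as description only, 1384 genes were at least 2-fold higher and 1005 at least 2-fold lower. The median difference over all genes was -0.04, and Pearson's r between the libraries across genes, which are not independent replicates, was 0.882. With a pseudocount of 5 RPKM, 656 genes were at least 2-fold higher and 405 at least 2-fold lower.

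Gene lists fixed beforehand described the pluripotency and LIF programs. Each list median is given with its percentile among 10000 random lists matched on size and expression. All 21 naive pluripotency genes had lower values at day 6, with a median log2 difference of -2.53 (percentile 0), and 18 of them were at least 2-fold lower, among them Fgf4, the autocrine growth factor of the inner cell mass (37.7 to 2.33 RPKM). All 12 core pluripotency genes were lower (median -1.87, percentile 0): Sox2 went from 212.2 to 25.8 RPKM, the Nodal co-receptor Tdgf1 from 332.9 to 44.3 RPKM, the TGF-beta family member Gdf3 from 60.2 to 10.6 RPKM, and Pou5f1, which encodes OCT4, from 772.3 to 179.7 RPKM. Of 15 LIF and STAT3 pathway genes, 10 were lower (median -1.33, percentile 0). The list shares 4 of these lower genes, Gbx2, Klf4, Tbx3 and Tfcp2l1, with the naive list, so the results overlap. They included the receptor gene Lifr (8.19 to 1.00 RPKM), the feedback inhibitor Socs3 (25.5 to 4.57 RPKM) and the STAT3 target genes Tfcp2l1 (23.6 to 3.05 RPKM) and Gbx2 (20.7 to 2.45 RPKM). The 11 formative and primed epiblast genes did not stand apart as a list (median 0.17, percentile 77.7). Their largest differences went both ways, with the tight-junction gene Cldn6 at 31.9 and 181.9 RPKM and the transcription factor genes Otx2 at 9.56 and 1.45 RPKM, Foxd3 at 7.08 and 0.879 RPKM and Zic2 at 9.49 and 2.82 RPKM.

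Lineage lists showed which programs were higher at day 6. All 13 primitive streak and mesoderm genes at 1 RPKM or more in at least 1 library had higher values (median 1.93, percentile 100). They included the streak factor T (Brachyury, 2.26 to 60.2 RPKM), the homeobox gene Mixl1 (0.155 to 7.33 RPKM) and Hand1, a factor of extraembryonic and lateral mesoderm (0.437 to 9.32 RPKM). Mixl1, Wnt3, Evx1, Kdr, Hand1, Msgn1 and Snai2 were under 1 RPKM at day 0. They passed the filter only through day 6 and could only be higher. T, Eomes, Fgf8, Bmp4, Snai1 and Twist1 passed it at day 0 and were also higher. Mesp1, Gsc, Wnt3a, Pdgfra, Hand2 and Tbx6 stayed under 1 RPKM in both libraries. Of 12 cardiac and smooth muscle genes, 11 were higher (median 2.64, percentile 100). The largest were smooth muscle and cytoskeletal genes: Acta2 at 12.9 and 408.5 RPKM, Tagln at 63.1 and 1169 RPKM, Cnn1 at 4.02 and 55.5 RPKM and Tpm1 at 216.9 and 1908 RPKM. Cardiac members differed: the cardiac actin gene Actc1 was at 0.766 and 9.62 RPKM, Nkx2-5, Tnnt2 and Myl4 reached 1.08, 1.74 and 1.84 RPKM at day 6, Myl7 was lower (2.50 to 1.28 RPKM), and Gata4, Tbx5 and Myh6 stayed under 1 RPKM. These members were named after their values were seen. Of 19 genes of extracellular matrix and epithelial-mesenchymal transition, 18 were higher (median 1.28, percentile 100). Among them were the collagens Col1a1 (1.22 to 21.7 RPKM) and Col1a2 (0.464 to 6.82 RPKM), the proteoglycan Dcn (0.204 to 8.17 RPKM) and the intermediate filament Vim (80.6 to 451.6 RPKM). Members under 1 RPKM at day 0, such as Col1a2 and Dcn, could only be higher. The epithelial cadherin gene Cdh1 was also higher (164.3 to 281.6 RPKM) and the transition factor gene Zeb1 was lower (1.84 to 0.675 RPKM), both named after their values were seen. The trophoblast list (9 of 11 higher, median 2.17, percentile 100) was led by keratins, which are not specific to trophoblast: besides Krt8 and Krt18, Krt7 was at 3.87 and 92.4 RPKM and Krt19 at 15.6 and 262.2 RPKM. Other members, named after their values were seen, went both ways. The transcription factor genes Cdx2 (1.79 to 9.36 RPKM) and Gata3 (0.516 to 4.15 RPKM) were higher. Tfap2c was lower (13.1 to 4.93 RPKM), and the trophoblast genes Elf5, Tpbpa, Prl3d1 and Plac1 stayed under 1 RPKM.

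Of 7 endoderm genes above 1 RPKM, 5 were higher and 2 lower (median 2.14, percentile 99.99). Its largest members, Col4a1 (8.69 to 72.2 RPKM), Col4a2 (5.21 to 51.5 RPKM), Sparc (55.0 to 386.4 RPKM) and Dab2 (2.27 to 13.4 RPKM), are basement membrane or adaptor genes. The lower ones were the laminin gene Lama1 (6.57 to 1.24 RPKM) and the apolipoprotein gene Apoe (1012 to 567.3 RPKM), named after their values were seen. The factors Sox17, Foxa2 and Gata6 stayed under 1 RPKM, and with all 19 genes the median was -1.004e-06. Of 9 neuroectoderm genes, 6 were lower (median -0.75, percentile 0.48), including the neural factors Pax6 (20.3 to 0.880 RPKM) and Sox1 (5.06 to 0.199 RPKM). The intermediate filament genes Vim and Nes (10.6 to 36.1 RPKM) were higher. Among genes with at least 5 RPKM in 1 of the libraries, this median was -0.11 and no longer stood apart, nor did it without the filter on low values (-0.00535). Only 3 of 18 Hox genes with a value reached 1 RPKM. They were higher as a list (median 1.54, percentile 98.1), with Hoxd9 at 0.346 and 3.91 RPKM and Hoxb9 at 0.519 and 3.42 RPKM. Hoxd9 and Hoxb9 were under 1 RPKM at day 0 and could only be higher. This call was lost without the filter on low values (median 0.0896), at a minimum of 5 RPKM (percentile 90.1) and with the highest transcript per gene (percentile 95.6).

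**Figure D1:**
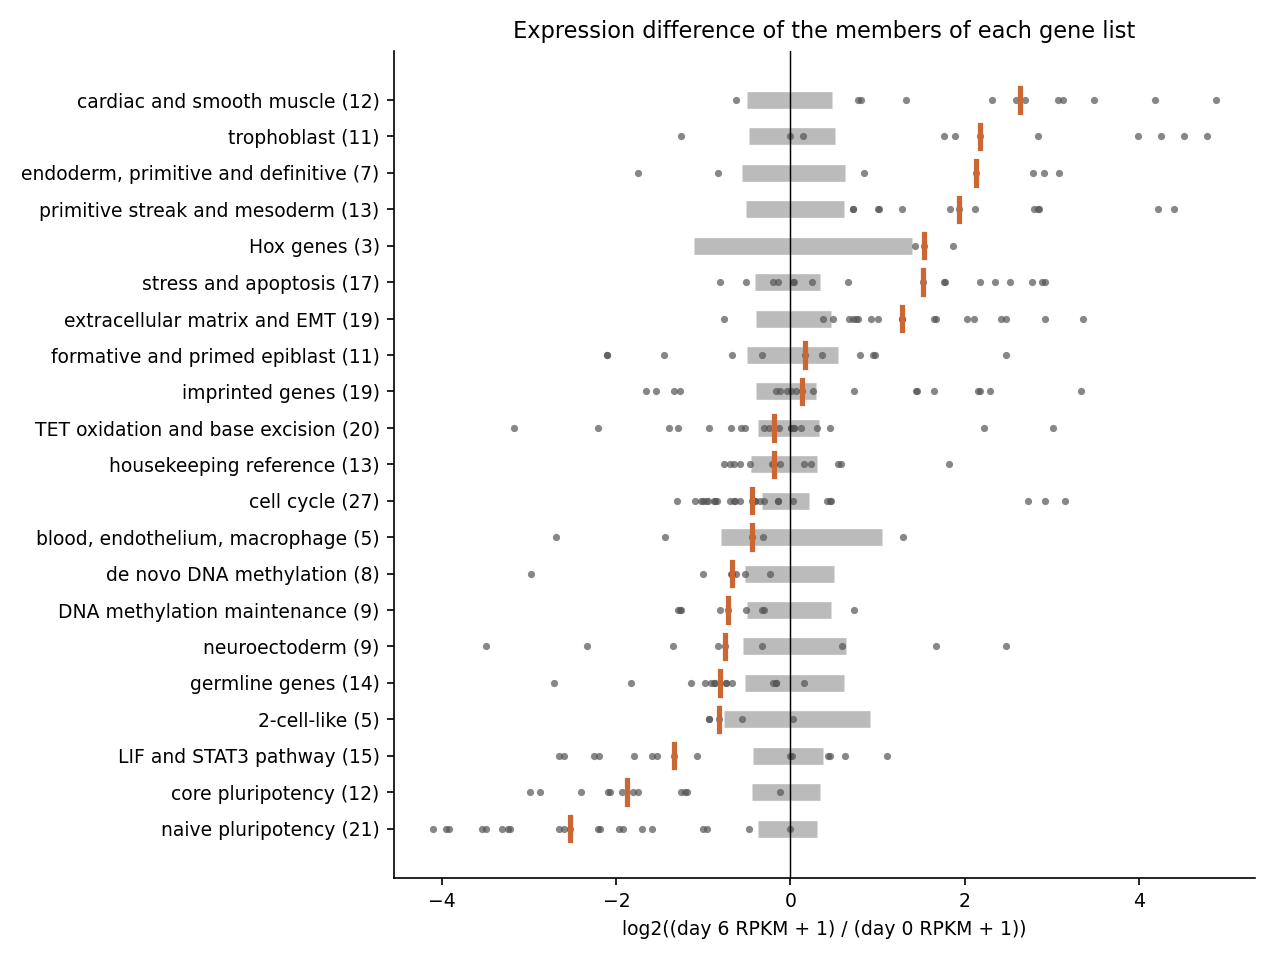
Log2 difference (day 6 RPKM + 1 over day 0 RPKM + 1) of each list member at 1 RPKM or more in at least 1 library (points), with the list median (orange bar) and the central 95% of medians of matched random lists (grey bar); numbers of members are in brackets. List medians run from -2.53 for naive pluripotency to 2.64 for cardiac and smooth muscle.

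The next question was whether the enzymes that write, keep and remove DNA methylation differed between the states. Of 9 maintenance genes, 8 had lower values at day 6 (median -0.72, percentile 0.12). The maintenance methyltransferase gene Dnmt1 (chromosome 9, 20907209 to 20959888) was at 62.8 and 35.3 RPKM, its partner Uhrf1, which binds hemimethylated DNA, at 62.4 and 37.5 RPKM, and the chromatin remodeler Hells at 109.8 and 44.2 RPKM. Its activator Cdca7 was at 50.1 and 20.3 RPKM and the deubiquitinase Usp7 at 118.1 and 48.7 RPKM. Differences were smaller for the replication genes Lig1 (-0.51) and Pcna (-0.33) and for Zbtb24 (-0.30), and Uhrf2 was higher (15.1 and 25.7 RPKM). All 8 measured de novo methylation genes were lower (median -0.67, percentile 0.53). The catalytically inactive cofactor Dnmt3l (chromosome 10, 78041947 to 78063622) went from 130.6 to 15.7 RPKM, the methyltransferases Dnmt3a from 11.8 to 5.35 RPKM and Dnmt3b from 50.1 to 31.2 RPKM. The histone methyltransferase genes Ehmt2 (-0.69), Nsd1 (-0.67), Setdb1 (-0.63), Ehmt1 (-0.52) and Setd2 (-0.24) made up the rest.

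The 20 genes of TET oxidation and base excision repair did not stand apart as a list (median -0.19, percentile 20.1), but their members differed widely. The dioxygenase gene Tet1 (chromosome 10, 62804570 to 62908996) was at 37.2 RPKM at day 0 and 3.25 RPKM at day 6, and Tet2 at 8.47 and 1.04 RPKM, while Tet3 was at 1.97 and 1.99 RPKM. Lower values were also seen for Parp1 (-1.39), the glycosylase genes Neil2 (-1.29), Ung (-0.94) and Mbd4 (-0.68), Lig3 (-0.57) and Neil3 (-0.52), and smaller ones for Apex1 (-0.31), Xrcc1 (-0.25) and Tdg (-0.13). Neil1 (0.01), Idh1 (0.04), Idh2 (0.04), Smug1 (0.12), Polb (0.30) and Gadd45a (0.46) were level or higher, and the stress-response genes Gadd45b (13.1 to 65.2 RPKM) and Gadd45g (6.23 to 57.5 RPKM) were far higher.

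Germline genes known to be silenced by promoter methylation were lower in 13 of 14 cases (median -0.80, percentile 0.22). They included the synaptonemal complex gene Sycp3 (37.2 to 4.83 RPKM), the meiotic gene Hormad1 (3.13 to 0.156 RPKM), Rhox13 (1.77 to 0.253 RPKM) and Stk31 (3.11 to 1.08 RPKM). Members under 1 RPKM at day 6, among them Hormad1 and Rhox13, passed the filter only through day 0 and could only be lower. Among genes with at least 5 RPKM in 1 of the libraries, the median was -0.16 (percentile 38.7) and the list no longer stood apart. The 2-cell-like list rested on 5 genes, with Zscan4c (2.73 to 0.949 RPKM), Zscan4f (2.70 to 0.938 RPKM), Zscan4d (1.76 to 0.566 RPKM) and Zscan4a (1.55 to 0.735 RPKM) lower (median -0.82, percentile 1.85). These Zscan4 genes were under 1 RPKM at day 6 and could only be lower. The Zscan4 genes are near-identical copies whose reads cannot be assigned with certainty, and this list lost its call with a pseudocount of 5 RPKM (median -0.28) and turned direction at a minimum of 5 RPKM (median 0.0318).

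The central question of the series was how DNA methylation and its symmetry across the strands differed between undifferentiated and differentiated cells. CpG methylation was higher at day 6. The methylation level over all dyads was 86.4% at day 0 and 91.6% at day 6, a difference of 5.19 percentage points with a 95% interval from 5.10 to 5.31. Fully methylated dyads made up 80.6% and 87.5% of dyad reads, and unmethylated dyads 7.85% and 4.36%. The difference was spread over the genome: the level was higher at day 6 in 2543 of 2553 blocks of 1 Mb. Fisher's exact test on the pooled reads returned p = 0, below the smallest number the computation can hold. All intervals given for methylation come from resampling 1 Mb blocks of the genome. They cover variation between regions of the genome and counting error within a library, but no variation between cultures or libraries. PCR reads are not independent molecules.

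Hemimethylated dyads, in which 1 strand has yet to be methylated after replication or has lost its mark, were fewer at day 6. Their share was 11.5% at day 0 (interval 11.5 to 11.6) and 8.12% at day 6 (interval 8.08 to 8.16), a difference of -3.40 percentage points (interval -3.44 to -3.36). Among dyads with any methylation, the hemimethylated share was 12.5% and 8.49%, a difference of -4.01 points (interval -4.06 to -3.96). A loss of unmethylated dyads alone would raise the share over all dyads, so it does not account for the lower share. Methylation fidelity, the share of dyads with the same state on both strands, was 88.5% at day 0 and 91.9% at day 6. Fidelity and the hemimethylated share depend on the level, since fewer dyads can be hemimethylated as methylation nears completeness. Whether symmetry differed beyond the difference in level was not tested. The hemimethylated share was lower at day 6 in 2408 of the 2553 blocks. At the 148825 dyads with the same number of reads in both libraries, the level differed by 5.16 points and the hemimethylated share by -3.28 points.

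Annotated parts of the genome shared the direction but not the size of the difference. The level went from 87.9% to 92.6% at intergenic dyads, from 87.8% to 92.9% in introns and from 84.4% to 91.0% in exons. Promoters of protein-coding genes were at 41.4% and 48.3%, the lowest of these 4 classes. Within promoters, dyads of low or intermediate CpG density went from 49.2% to 57.6%, a difference of 8.40 points (interval 7.82 to 8.94). Promoter dyads of high CpG density, the CpG-island type of promoter, stayed at 4.76% and 5.31%, and the interval of that difference (-0.239 to 1.30) includes 0. Dyads of high CpG density outside promoters were at 15.7% and 23.3%, a difference of 7.57 points (interval 5.56 to 8.77). Hemimethylated dyads were fewer at day 6 in introns (11.7% and 8.08%), exons (10.5% and 6.996%) and intergenic sequence (11.8% and 8.68%), and repeat-masked dyads had 12.1% and 9.10%.

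**Figure D2:**
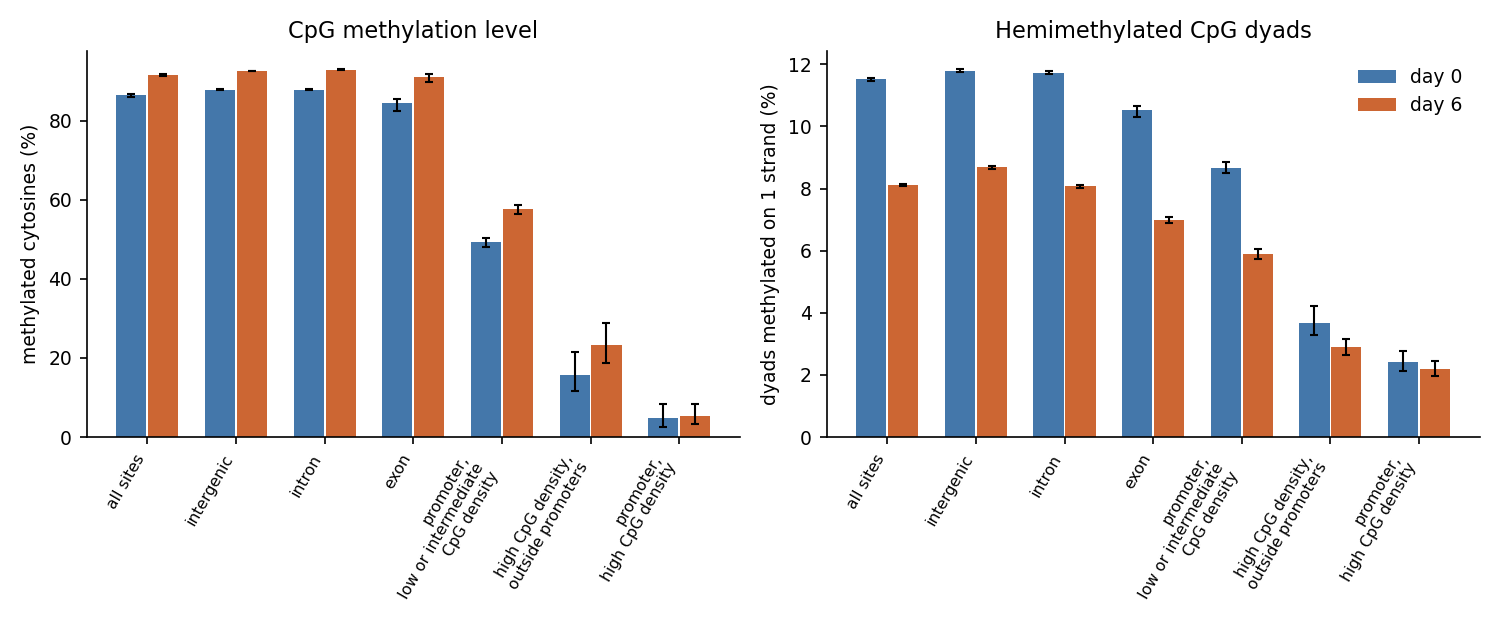
CpG methylation level (left, percent of cytosines) and hemimethylated dyads (right, percent of dyads) by annotated class at day 0 (blue) and day 6 (orange), 1 library each; bars show pooled values and error bars 95% intervals from resampled 1 Mb blocks. Levels are higher and hemimethylated shares lower at day 6 in every class except promoters of high CpG density, where the intervals of both differences include 0.

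Hemimethylated dyads were almost evenly divided between the strands. The strand named first in the data carried the methyl group in 49.9% of hemimethylated dyads at day 0 (interval 49.8 to 49.99) and in 49.8% at day 6 (interval 49.6 to 49.9), with p = 1.8e-10 and p = 3.1e-25 in exact two-sided binomial tests that take each read as independent.

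Single dyads and regions were compared next, to see where in the genome the libraries differed. Of 12719 promoters with at least 20 dyad reads in each library, 5160 had a higher and 1587 a lower level at day 6 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p at or under 0.05). Of 228278 windows of 10 kb, 121018 were higher and 22599 lower, and of 1883359 dyads, 386628 and 138976. Measured against the genome-wide odds ratio of 1.71, 3499 promoters were higher and 2598 lower, and 77248 windows were higher and 46923 lower. These counts treat reads as independent, but the libraries held an estimated 4.26 (day 0) and 2.95 (day 6) molecules per dyad, as read from hemimethylated dyads whose reads lie on 1 strand. These estimates give most weight to dyads with many reads. At dyads with 10 to 19 reads they were 3.06 (day 0) and 1.83 (day 6). With reads reduced to such effective molecules, 0 promoters, 0 dyads and 144 windows, all higher at day 6, passed. For dyads the 0 was in effect fixed in advance by the few molecules. Even a full switch could not pass the adjustment unless most dyads switched, so it does not show which dyads differ. For regions the tests with effective molecules also use 1 dyad per 200 bp and at least 5 molecules. They had little power at promoters: even Tcp11, at 0% and 100% of reads with 7 and 6 effective molecules, did not pass. Of the promoters and windows named next, Neil3 had too few molecules for that test and none of the others passed it, so their values describe the reads.

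Naive pluripotency promoters had a median gain in reads of 21.2 points over 7 promoters with at least 50 dyad reads, 5 of which were higher and 2 lower by the read-based test. The LIF and STAT3 list, which shares genes with it, had a median gain of 20.1 points over 6 promoters, 5 higher and 1 lower. Of all 8087 promoters with at least 50 reads, tested on their own, 3614 were higher and 1104 lower. The imprinted list gained 12.2 points over 12 promoters (8 higher, 1 lower), and the core pluripotency list 0 over 3. No list, the germline list below included, was set against promoters of like day 0 level. No gain is thus shown to be particular to its list. The promoter of Dppa5a (chromosome 9, 78367677 to 78369177) went from 15.1% to 66.4%, with 119 and 146 reads over 9 dyads, and that of Tcl1 (chromosome 12, 105222293 to 105223793) from 44.3% to 95.4%, with 227 and 313 reads over 17 dyads. Tfcp2l1 was at 51.6% and 73.7% and Dppa2 at 10.1% and 31.3%. Each of these promoters held no more than 16 effective molecules per library. Of 12 germline promoters, 9 were higher and 1 lower, with median levels of 85.3% and 94.4%: Sycp1 was at 69.9% and 94.9%, Tdrd1 at 47.5% and 62.7%, Hormad1 at 79.6% and 93.9% and Stk31 at 89.1% and 98.2%. Among methylation genes, the promoter of Usp7 was at 33.5% and 72.1%, of Zbtb24 at 31.9% and 45.8%, of Dnmt3b at 40.6% and 59.5% and of Neil3 at 29.8% and 50.4%. Uhrf1 (21.8% and 8.20%) was lower, Polb (15.97% and 22.4%) higher, and Lig3 (3.57% and 0%) lower. Dnmt3a (75.2% and 73.3%) and Tet1 (89.6% and 94.0%) did not pass the read-based test.

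Over all promoters, the largest positive differences in reads were at Tcp11 (chromosome 17, 28080139 to 28081639; 0% and 100% over 5 dyads), a gene of sperm function, Lefty1 (0% and 88.2%), a Nodal antagonist, Rfc1 (3.45% and 90.4%), Ccdc15 (9.80% and 91.9%) and Hsp90aa1 (6.33% and 85.9%). The largest negative ones were at the securin gene Pttg1 (98.3% and 33.0%), Gtse1 (62.7% and 0%), Rbbp8nl (92.5% and 33.2%), the olfactory receptor gene Olfr1448 (92.6% and 36.4%) and the iron-homeostasis gene Hfe (89.5% and 36.3%). None of the 10 passed with effective molecules, of which each held between 6 and 13 per library. The window with the largest gain, chromosome 11 from 4800000 to 4809999 at the tumor suppressor gene Nf2, went from 5.0% to 99.5%, and the one with the largest loss, chromosome 4 from 28150000 to 28159999 outside protein-coding genes, from 90.6% to 18.9%. Among single dyads, ranked by p, that at position 75086892 of chromosome 15 went from 56.3% to 95.1% with 1971 and 1820 reads. The dyad at position 70175649 of chromosome 13 went from 100% to 0% with 98 and 45 reads. Ranking by p favors deep dyads: the medians were 13 reads at day 0 and 16 at day 6. The cause of the extreme depth at the chromosome 15 dyad was not tested.

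Non-CpG methylation, which mouse embryonic stem cells carry mainly at CA, was compared to see whether it followed CpG methylation. It went the other way and was lower at day 6. Methylated calls at CA made up 2.52% of calls at day 0 and 2.22% at day 6, a difference of -0.295 percentage points (interval -0.300 to -0.290). The difference was largest at CAC (3.22% and 2.63%), and within it at ACAC (3.96% and 3.10%). CAG went from 2.56% to 2.28%, CAA from 2.31% to 2.11% and CAT from 2.11% to 1.93%. CC cytosines, the least methylated, were at 0.841% and 0.815%, a difference of -0.0258 points (interval -0.0287 to -0.0230), and CT cytosines at 1.13% and 1.05%. CCG did not differ beyond its interval (1.31% in both libraries). Over the deposited classes, the level was 1.81% and 1.65% at CAG and CTG together (a difference of -0.157 points) and 1.48% and 1.35% at the other non-CpG cytosines (-0.134 points), with Fisher's p returned as 0 for both. Calls from incomplete conversion were not subtracted, so these values are upper limits of methylation.

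**Figure D3:**
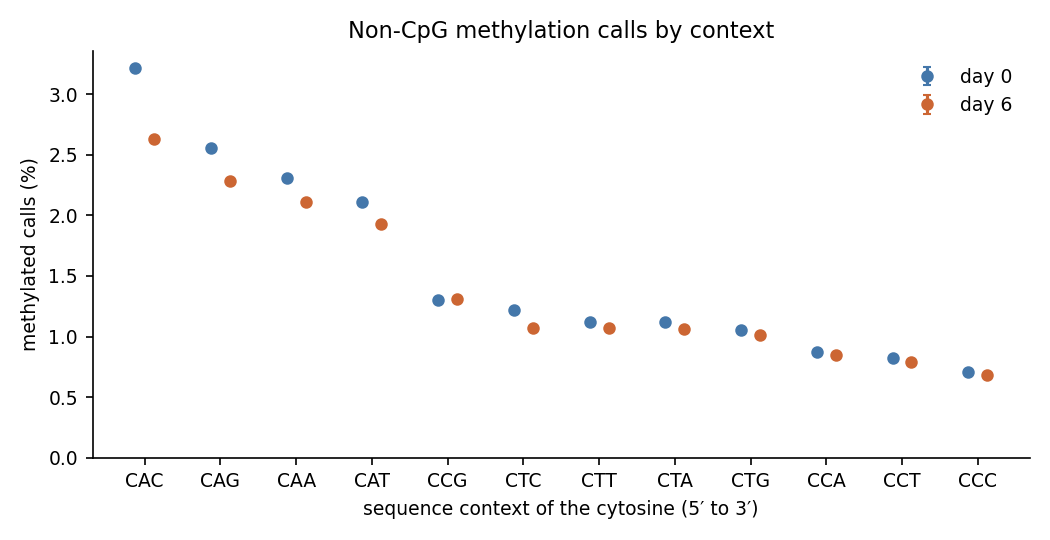
Methylated calls (percent of calls) at non-CpG cytosines by the cytosine and its next 2 bases at day 0 (blue) and day 6 (orange), 1 library each; error bars, 95% intervals from resampled 1 Mb blocks, are smaller than the points. CAC, CAG, CAA and CAT are the highest contexts in both libraries and are lower at day 6.

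Coverage by chromosome was compared to see whether the hairpin libraries sampled the genome evenly. Chromosome 8 had more covered dyads and reads than other autosomes: 24.7% of its reference CpG dyads were covered, 1.45 times the autosome median. Against autosomal windows of like CpG density and GC content, its reads per reference CpG were at a median ratio of 1.78 at day 0 (interval 1.69 to 1.84) and 1.70 at day 6 (interval 1.64 to 1.76). Chromosome X, present once in a male line, was at 0.223 and 0.243 of the autosome median in reads per reference CpG. These ratios were not matched on CpG density or GC content, unlike those of chromosome 8. Dyads with fewer than 5 reads in either library are absent, so they do not translate into copies. Leaving out chromosome 8, the CpG level differed by 5.20 points and the hemimethylated share by -3.40 points.

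**Figure D4:**
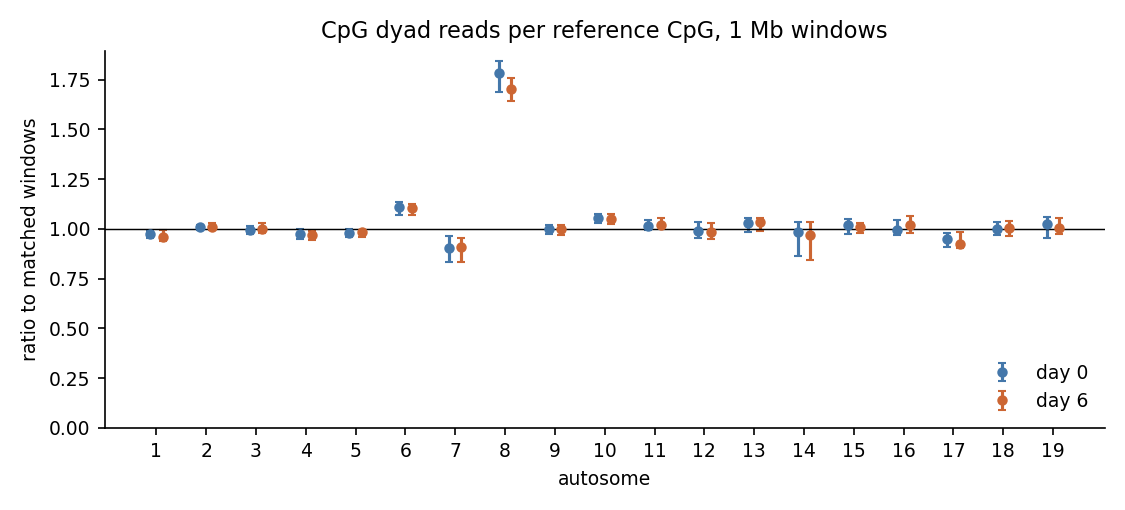
CpG dyad reads per reference CpG of each autosome as the median ratio of its 1 Mb windows to autosomal windows matched on CpG density and GC content, at day 0 (blue) and day 6 (orange), 1 library each; error bars are 95% bootstrap intervals over windows. Chromosome 8 lies at 1.78 at day 0 and 1.70 at day 6.

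The last comparison related promoter methylation to expression across genes within each state. Genes with unmethylated promoters were expressed at higher values in both libraries. At day 0, the median was 9.44 RPKM for 5343 genes with a promoter level of 20% or less, 1.69 RPKM for 3636 genes in between and 0.028 RPKM for 3115 genes at 80% or more. At day 6 the medians were 9.48, 3.74 and 0.0659 RPKM, and the class at 80% or more had grown from 25.8% to 34.5% of genes. Spearman's rho between promoter level and expression across 12094 genes, which are not independent replicates, was -0.541 at day 0 (interval -0.554 to -0.528, from resampled genes) and -0.508 at day 6 (interval -0.522 to -0.495). Between the difference in promoter level and the difference in expression, rho was -0.00868 over 7674 genes (interval -0.0317 to 0.0124), so no relation between the differences was detectable at this depth. With promoters of few molecules, the differences in level hold sampling noise that lowers such a correlation.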

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

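The effective-molecule, equal-read, chromosome 8 and bootstrap alternatives were chosen after the results were seen; all others were planned. The CpG level difference stayed between 5.01 and 5.28 points over 10 alternatives. Its upper end came from the conversion correction at the rate of the table named CHH. The difference in the hemimethylated share stayed between -3.41 and -3.28, and that in the hemimethylated share of methylated dyads between -4.28 and -3.94. The non-CpG differences stayed between -0.179 and -0.148 (CAG and CTG) and between -0.164 and -0.121 (other contexts) over 7 alternatives each. A minimum of 5 reads and the restriction to shared sites moved nothing, since the deposited sites already meet both. The block bootstrap, also counted in these numbers of alternatives, returns the main value by construction and adds only an interval. These 3 settings therefore do not test stability. For the strand shares, the minimum of 5 reads removes no site and the bootstrap changes only the interval, so neither tests their stability. Among genes named by the fixed rule that differed at least 2-fold, none reversed, and sign changes of smaller differences were not counted. Over all named genes, 605 values kept within 0.5 on the log2 scale and 93 moved further, under another pseudocount or with 1 transcript per gene.

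Called dyads numbered 205271 of 555478 tested at a minimum of 20 reads. They numbered 119271 of 1883359 when dyads with any methylation were counted, and 0 with effective molecules. That 0 was in effect fixed by the few molecules per dyad. Called windows numbered 317464 at 2 kb, where more regions are tested, and 144 with effective molecules, and called promoters 0. The region counts with effective molecules also use 1 dyad per 200 bp and at least 5 molecules, and which of these choices lowered them was not tested. With a pseudocount of 5 RPKM, 1061 genes differed at least 2-fold, since a larger pseudocount shrinks the differences of low genes.

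List medians that lost their call were, without the filter on low values, neuroectoderm (-0.00535), Hox genes (0.0896) and endoderm (-1.004e-06, in effect no difference). At a minimum of 5 RPKM, neuroectoderm (-0.11), Hox genes (1.43) and germline genes (-0.16) lost theirs, and the 2-cell-like median reversed to 0.0318. With a pseudocount of 5 RPKM the 2-cell-like list was at -0.28, and with the highest transcript per gene the Hox list at 1.18. These filters change which genes are in a list; beyond that the cause was not tested. With promoters of 500 bp each way, Spearman's rho was -0.579 at day 0 and -0.562 at day 6, and the cause was not tested. No paired analysis was possible because the labels carry no replicate numbers and each state has 1 library.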

Other observations

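Of the tests in this part, those of conversion at CC, of losses at single cytosines, both tests of CA methylation and the resampling of blocks were chosen after the result was seen, the last before its interval was known, and the tests of chromosome 8 after its coverage was seen.

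Cell cycle genes were lower as a list at day 6 (20 of 27, median -0.44, percentile 0.325). The replication licensing genes Mcm2 (156.5 to 72.5 RPKM), Mcm3 (145.9 to 72.4 RPKM) and Mcm5 (170.4 to 86.3 RPKM), named after their values were seen, and the S-phase factor E2f1 (13.7 to 4.95 RPKM) were lower. The cyclin-dependent kinase inhibitor genes Cdkn2b (1.57 to 21.8 RPKM), Cdkn1a (12.8 to 104.2 RPKM) and Cdkn2a (6.69 to 49.9 RPKM) were higher. The stress and apoptosis list was higher (13 of 17, median 1.52, percentile 100), with the stress factor Atf3 at 2.00 and 21.2 RPKM, the immediate early gene Fos at 2.71 and 24.4 RPKM and the death receptor gene Fas at 0.358 and 6.80 RPKM. Cdkn1a is in both lists.

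Imprinted genes did not stand apart as a list (12 higher and 7 lower, median 0.14, percentile 88.8). The largest differences were at the fetal growth factor gene Igf2 (13.9 to 149.9 RPKM), Nnat (3.67 to 21.9 RPKM), Peg10 (71.4 to 325.3 RPKM) and Peg3 (9.83 to 47.1 RPKM), which are expressed from the paternal allele. Another paternally expressed gene, Impact, was at 90.4 and 80.6 RPKM. Genes expressed from the maternal allele went both ways: the neighboring noncoding RNA genes Meg3 (237.3 to 74.4 RPKM), Rian (101.1 to 39.4 RPKM) and Mirg (19.8 to 6.15 RPKM) were lower, H19 (0.876 to 4.13 RPKM) and Igf2r (19.7 to 23.8 RPKM) were higher, and Cdkn1c was at 48.0 and 48.1 RPKM. Impact and these maternally expressed genes were named after their values were seen, and no test of parental origin was made. The housekeeping list (median -0.19, percentile 34.8) and the blood, endothelium and macrophage list (median -0.44, percentile 11.3) did not stand apart. Among their members, B2m was at 49.5 and 178.4 RPKM, Gapdh at 748.3 and 442.0 RPKM, Eef1a1 at 4888 and 3013 RPKM and Rpl13a at 971.0 and 617.0 RPKM. Pecam1, which embryonic stem cells also express, was at 9.96 and 0.689 RPKM, Tek at 3.46 and 0.640 RPKM, Runx1 at 0.300 and 2.17 RPKM and Cd34 at 1.41 and 0.768 RPKM.

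Dyads were more methylated and less often hemimethylated at day 6, while transcripts of Dnmt1, Uhrf1, Dnmt3a, Dnmt3b and Dnmt3l were lower. On the side of removal, Tet1 (37.2 to 3.25 RPKM) and Tet2 (8.47 to 1.04 RPKM) were also lower. Tet3 was level (1.97 and 1.99 RPKM), and the TET and base excision list did not stand apart. Whether any of these transcripts bears on the methylation difference was not tested. Poorer conversion at day 6 would raise calls at CC cytosines, but these differed by -0.0258 points. Single-cytosine losses that bring the day 6 dyads to the day 0 level would give 17.0% hemimethylated dyads at day 0, above the 11.5% observed, so they do not explain the day 0 library alone. Chance among few PCR-copied molecules is argued against by the lower bound of the resampled level difference, 5.10 points. A difference of the states, such as slower division leaving more time for maintenance, may underlie the pattern but was not tested, and a difference between 1 library and the other of another kind stays open.

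CA methylation was lower at day 6 while CpG methylation was higher. If better conversion at day 6 were the cause, CA and CC would differ by the same number of points, but the CA level over the CC level differed by -0.270 points (interval -0.275 to -0.264). A few highly methylated repeats are argued against by the -0.294 points seen at CA outside repeat-masked sequence, close to the -0.301 points inside it. Lower activity of the de novo enzymes, which methylate CA, is a candidate explanation in line with the lower Dnmt3a and Dnmt3l transcripts, but it was not tested, and state and library are confounded.

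Chromosome 8 had more covered dyads and more reads than the other autosomes in both libraries. Against windows of like CpG density and GC content, its 124 windows of 1 Mb had a median ratio of 1.47 in covered dyads (interval 1.41 to 1.49). Its CpG density and GC content thus do not account for the excess. The density of MseI and MluCI sites was not matched. A few segments are argued against by 94.4% (day 6) and 97.6% (day 0) of windows lying above their matched median in reads; in covered dyads, the measure named beforehand, 87.9% did, short of the 90% set for it, and reads were turned to after both had been seen. An extra copy of chromosome 8 in some or all cells, a known recurrent change in cultured mouse embryonic stem cells, may be the source: its 2 conditions, at least 90% of windows above in reads (94.4% in the lower library) and a ratio of mean reads per covered dyad above 1 (1.16 in the lower library), were met, but they largely restate the excess that prompted them and add little support. Other causes that act on a whole chromosome were not tested, and the ratio does not translate into copies because dyads with fewer than 5 reads are absent.

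The gain at naive pluripotency promoters led to the hypothesis that genes with lower expression at day 6 gained promoter methylation more than others. The median gain of 591 genes at least 2-fold lower was 3.61 points, at percentile 96.045 of random sets matched on the day 0 promoter level, which misses the upper bound set beforehand. Genes at least 2-fold higher (871) had a median gain of 2.60 points, at percentile 28.0. The hypothesis was thus not borne out at that bound, which does not show that the gains are alike.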
